A study of Mus musculus with 5 samples.

How the data were processed

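H3K14ac, the acetylation of lysine 14 of histone H3, was profiled by CUT&Tag, in which an antibody directs the Tn5 transposase to cut and tag nearby DNA. The cells were LSK cells (lineage-negative, Sca-1-positive, Kit-positive), a bone marrow fraction that holds blood stem cells and early progenitors, sorted from male C57BL/6 mice. Per the labels, Mx1-cre was induced with poly(I:C), the knockout libraries came from mice homozygous for the def allele of Hbo1, and the control libraries from heterozygous mice. The series lists 5 libraries; the HBO1 (KAT7) library of control cells was not analysed here, and the 4 H3K14ac libraries formed 2 groups of 2.

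The deposited files hold whole-number read counts per Entrez gene, counted by the authors over 3 region classes, per the file headers: the 5 kb upstream of the start site, the gene body, and the 5 kb downstream of the end. The submitters' processing notes name featureCounts and the mm10 build. The aligner, annotation release, duplicate handling, read filters and any spike-in were not given in the sources used here. The deposited gene body length in bp, a column the authors wrote beside the counts, was used for counts per kb. The series tables and the per-library files held the same values for 27179 genes, with 0 differing. Symbols were taken by Entrez identifier from a RefSeq table of GRCm38.p6, which named 25275 genes (93.0%) and left 1904 without a symbol. Positions, GC content and CpG ratios came from the same assembly and covered 25201 genes (92.7%); the deposited gene length was within 20% of the annotated one for 82.6% of genes.

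Each region class was tested on its own with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, after filterByExpr (minimum count 10, minimum total 15) and TMM scaling, with no covariate. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a region class, at a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values are TMM scaled. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with the preset correlation of 0.01 and again with an estimated correlation, and with fry, each adjusted over 15 lists within a region class. With an estimated correlation, camera tests on the residual degrees of freedom that 4 libraries leave, so it has little power to pass a list. Most estimates lay above the preset, up to 0.632 upstream (cell cycle), 0.807 over gene bodies (histones) and 0.641 downstream (histones). Camera p-values with the preset therefore treat genes that vary together as nearly independent, and can be far too small. Shares of counts and ratios to receptor genes were compared by exact two-sided permutation over 6 assignments, for which the smallest possible p is 0.333. Intervals of shares are 95% Wilson intervals and cover counting error only. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used for these values and the plots.

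The gene lists were fixed before the data were examined: HSC regulators, erythroid and megakaryocyte genes, granulocyte and monocyte genes, lymphoid genes, stromal and endothelial genes, interferon response genes, cell cycle and replication genes, the HBO1 complex and acetyltransferases, silent developmental regulators, Hox genes, ribosomal proteins, oxidative phosphorylation, proteasome, replication-dependent histones, and olfactory and vomeronasal receptors. The histones were matched through older symbols (69 genes), and 28 of the 30 erythroid and megakaryocyte genes were found. Named genes were also chosen by a rule fixed before the data were examined. In the upstream and gene body comparisons they were the 10 genes that fell most and the 10 that rose most among those past the threshold, with both knockout libraries on the same side of both controls and a mean log2 CPM above the median. In the downstream comparison 5 and 5 were taken. Predicted and unnamed genes were passed over. Kat7, up to 4 members of each list with the smallest p, and every HSC regulator past the threshold were added.

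The alternatives fixed beforehand were library totals, DESeq2 1.42.0 size factors, totals pooled over the 3 region classes, scaling on receptor genes, the DESeq2 Wald test, a later variant of the quasi-likelihood fit, limma-trend, no filter, a mean count of at least 50, each library left out in turn, and the replicate number as a block. A GC correction (loess span 0.3), a crossed block and the removal of regions that hold another gene's start site were added after seeing the data. The edgeR step was tested on simulated counts with 200 genes drawn for a known change. At a 4-fold change it recovered 55.6% of the changed genes among 22788 tested upstream, 75.8% among 21122 gene bodies and 62.1% among 20908 downstream regions. Unchanged genes made up 0%, 7% and 4.1% of those calls. At a 2-fold change it recovered 0% upstream among 22785, 10.7% in gene bodies among 21131 and 0.5% downstream among 20895. With so few genes changed, the adjusted threshold is stricter than in the data, where many more genes passed. These recoveries therefore do not carry over to the comparison itself.

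The gene body totals were 12386891 and 10572534 counts in the control libraries and 4723549 and 6031189 in the knockout libraries. Upstream totals ran from 869859 to 1164409 and downstream totals from 677213 to 1260351. Replicates differed beyond counting noise, with a chi-square per degree of freedom of 2.39 (control) and 6.76 (knockout) upstream. This does not tell biological from technical spread. Each library was kept as a sample.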

Results

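H3K14ac counts were available for 2 control and 2 Hbo1 knockout libraries of LSK cells. HBO1, encoded by Kat7, is a lysine acetyltransferase that acetylates H3K14, and the comparison asks where this mark differs when the enzyme is deleted in blood stem and early progenitor cells. The libraries held between 4723549 and 12386891 counts over gene bodies, with the knockout libraries the shallower. Nothing in the labels says whether libraries came from separate mice, so p-values measure the spread between these samples, which may be technical. No spike-in was stated, so each fold is relative to the scaling of the libraries. Compared with TMM, scaling on olfactory and vomeronasal receptor genes, which blood cells are not known to use, moved the median log2 fold of all genes by 0.92 upstream, 0.65 in gene bodies and 0.3 downstream. Library totals moved it by -0.18, 0.34 and -0.2, and totals pooled over region classes by 0.55, 0.22 and -0.01. Reads copied by PCR are not independent molecules.

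Kat7 itself (Entrez 217127, chromosome 11, 95271853 to 95310246, GRCm38) had an upstream H3K14ac level of 42.9 ± 3.2 CPM in controls and 21.9 ± 3.57 CPM in knockouts (SD, n = 2 each), a log2 fold of -0.97 ± 0.47 (SE) that did not pass (edgeR adjusted p = 0.0872). The log2 fold of Kat7 was -0.05 with receptor scaling and -0.41 with pooled totals, and passed with a GC correction added after seeing the data (-1.07). Over its gene body the mark was higher in the knockouts, with a log2 fold of 1.06 ± 0.32 (edgeR adjusted p = 0.00668). That call of Kat7 was lost with receptor scaling (log2 fold 1.79), without either control (1.07 and 1.04) and without knockout replicate 1 (0.39). Downstream the log2 fold was -0.46 ± 0.47 (edgeR adjusted p = 0.548), and for Kat7 it was -1.47 without knockout replicate 1 and 0.29 without knockout replicate 2. Counts of a histone mark over the whole gene do not check the deletion.

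H3K14ac reads lay more often upstream of genes in the knockout libraries. The upstream share of counts was 8.14% ± 0.40 in controls and 13.94% ± 3.60 in knockouts (SD, n = 2 each). The gene body share was 83.13% ± 0.70 in controls and 76.03% ± 4.22 in knockouts, and the downstream share was 8.72% ± 0.30 and 10.03% ± 0.62. With 1 library left out the difference ranged from 3.25 to 8.34 points upstream, -10.09 to -4.13 over gene bodies and 0.88 to 1.75 downstream. By library, the gene body share was 83.63% and 82.64% in controls and 73.04% and 79.01% in knockouts. The upstream share was 16.48% in knockout replicate 1 (95% Wilson interval 16.46 to 16.51) and 11.39% in knockout replicate 2 (11.37 to 11.42). In each region class both knockout libraries lay outside both controls, and the exact two-sided permutation p was 0.333, the smallest this design allows. Without the 1% of genes with the highest counts the downstream difference went from 1.31 to 0.52 percentage points.

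**Figure D1:**
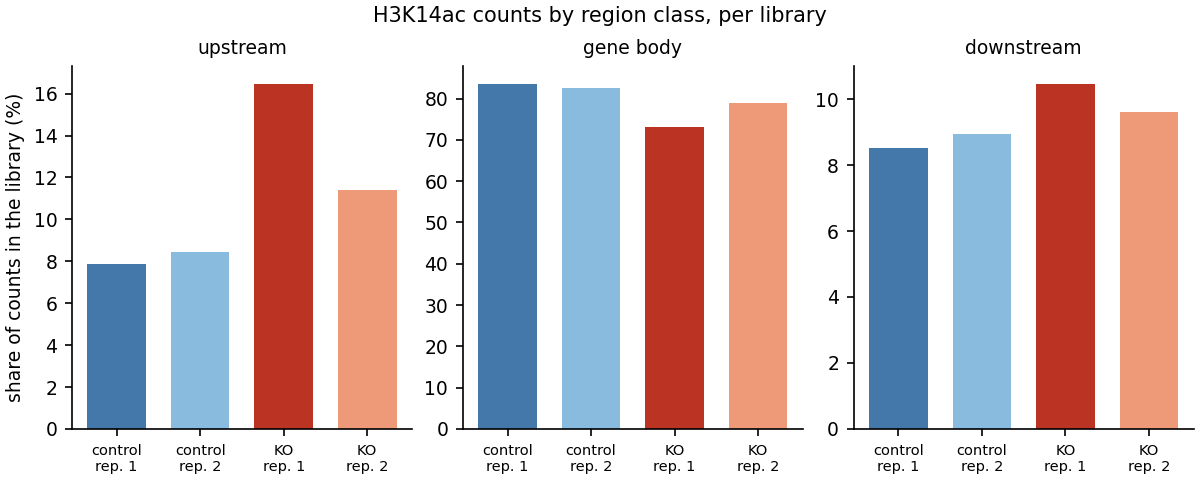
Share of each library's counts (%, vertical axis from 0) in the upstream, gene body and downstream region classes, 1 bar per library. The upstream bars of the knockout libraries reach 16.48% and 11.39%, against 7.86% and 8.43% in the controls.

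Upstream of the start site, H3K14ac rose in the knockouts at 5557 genes and fell at 3328. Among the named genes that rose most was Per1, a circadian clock gene (29.0 ± 16.4 CPM in controls, 984 ± 638 in knockouts, SD, n = 2 each; log2 fold 5.08 ± 1.39 SE, edgeR adjusted p = 0.00197). Zfp36, which encodes an RNA-binding protein of mRNA decay, rose by a log2 fold of 4.98, and H2-D1, a class I histocompatibility gene, by 4.55. Sde2, Ssbp4, Pitpnm1, Zc3h10, Amdhd2 and Tnrc18 were also among the 10, with log2 folds between 4.60 and 4.89. Among those that fell most were Plcz1, a sperm phospholipase gene (chromosome 6, 139987396 to 140041488; 98.91 ± 60.19 CPM in controls, 14.55 ± 4.50 in knockouts; log2 fold -2.75 ± 0.54 SE, edgeR adjusted p = 1.3e-05), Vmn2r22, a vomeronasal receptor (-2.49), and Npsr1, a neuropeptide receptor (-2.43). Svopl, Themis3, Akr1c14, Wipf3, Prl6a1 and Zmat4 fell by log2 folds between -2.67 and -2.26. The upstream regions of Pitpnm1, Zc3h10 and Plcz1 hold the start site of another gene. Of upstream regions that hold one, 50.2% of 2820 rose, against 21.0% of 18991 that hold none.

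By edgeR, 8885 of 23200 upstream regions passed the threshold, 5557 higher and 3328 lower in the knockouts, and in 77.8% of regions the 2 groups did not overlap, against 33.3% by chance. The regions without overlap were split the other way, with 8780 higher and 9265 lower, and the median log2 fold of all upstream regions was -0.09. The 33.3% is the chance for 1 region taken alone. All regions share the same 4 libraries, so the excess, here and in the other region classes, is not a test across regions. The split of calls depended on scaling. It was 4369 higher and 3983 lower with library totals and 7668 and 458 with totals pooled over region classes. Receptor scaling gave 7185 and 38. Another test, the DESeq2 Wald test with its own size factors, gave 4521 and 1454, where these size factors in edgeR gave 5825 and 2774. With 1 library left out the count was 0 without knockout replicate 1 (5770 at an unadjusted p under 0.05), 73 without control replicate 1, 914 without control replicate 2 and 2303 without knockout replicate 2, and all 10 named rises lost their call without knockout replicate 1 or either control. All 10 named falls lost it without either knockout replicate or control replicate 1. The log2 folds of the 10 rises ran from 3.45 (Amdhd2) to 4.22 (Per1) without knockout replicate 1. They ran from 4.02 (H2-D1) to 4.92 (Pitpnm1) without control replicate 1 and from 4.43 (Tnrc18) to 5.82 (Per1) without control replicate 2. Receptor scaling ended 5 of the 10 rises, Per1 and Zfp36 among them, and 2 of the 10 falls, Prl6a1 and Zmat4.

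Among HSC regulators, genes with roles in blood stem cells, 16 of 38 tested upstream regions rose, 1 fell and 21 did not pass, and adjusted over the list alone the counts were also 16 and 1. Risers included the transcription factor genes Gata2 (log2 fold 1.5 ± 0.55 SE), Tal1 (2.80 ± 0.80), Meis1 (1.69 ± 0.54) and Lyl1 (3.51 ± 0.65), and the immediate-early genes Fos (4.46 ± 1.15), Egr1 (3.77 ± 0.87) and Junb (3.57 ± 0.91). The list's camera test passed (adjusted p = 9.1e-04) but not with an estimated correlation (adjusted p = 0.548). The list was chosen partly from genes this study is known for, so it is not independent evidence of a direction. Each of the 17 calls was lost without knockout replicate 1, and likewise without either control library. The log2 folds of the risers ran from 1.07 (Meis1) to 4.17 (Zfp36) without knockout replicate 1. They ran from 1.01 (Hoxa9) to 4.70 (Zfp36) without control replicate 1 and from 1.42 (Hoxa9) to 5.33 (Zfp36) without control replicate 2. Receptor scaling ended 7 of the 17 calls. Among these were Tal1, Fos and Junb, whose log2 folds it raised to 3.90, 5.56 and 4.69. The GC correction ended the call of Gata2 (1.09).

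In 6 lists of widely used genes, calls of a rise upstream far outnumbered those of a fall. Their start sites had median observed over expected CpG ratios from 0.70 to 0.88. Of all 9350 upstream regions of genes with a CpG-rich start site (ratio of at least 0.6), 43.4% rose and 3.1% fell. Whether these lists moved beyond that class was not tested. Among replication-dependent histones 31 of 37 tested rose and 1 fell (31 and 2 adjusted over the list alone), with a median log2 fold of 2.96; H1f2, a linker histone gene, rose by 2.99 ± 0.51. Histone genes are near-identical copies in clusters, so their counts are uncertain. Among cell cycle and replication genes 24 of 36 rose and 0 fell (26 and 0 over the list alone), with Pcna, the replication clamp (2.94 ± 0.54), and Orc1, of the origin recognition complex (2.91 ± 0.51). Ribosomal protein genes gave 36 higher and 1 lower of 55 (39 and 2), oxidative phosphorylation 38 and 0 of 71 (40 and 0), proteasome 17 and 0 of 38 (19 and 0), and the HBO1 complex and acetyltransferases 11 and 0 of 18 (12 and 0). Ing4, a subunit gene of the HBO1 complex, rose by 4.16 ± 0.57 and Ep300, another acetyltransferase, by 2.41 ± 0.50. Camera passed for each of these 6 lists, with adjusted p between 1.3e-21 and 0.00128, and for none with an estimated correlation (adjusted p = 0.548 for each).

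Olfactory and vomeronasal receptor genes went the other way, with 244 of 813 tested upstream regions lower and 0 higher (178 and 0 adjusted over the list alone) and a median log2 fold of -0.96, which receptor scaling sets to -0.02 by construction. Stromal and endothelial genes gave 4 lower and 1 higher of 20 (4 and 1 over the list alone), among them Dcn (-2.04 ± 0.49) and Lum (-1.90 ± 0.49), both matrix proteoglycan genes. Their median of -0.60 became 0.33 with receptor scaling, which ended the calls of Dcn and Lum. Camera passed for both lists (adjusted p = 6.0e-15 and 0.0296) and for neither with an estimated correlation (adjusted p = 0.548 and 0.563). Camera did not pass for granulocyte and monocyte genes (7 higher, 0 lower of 24; adjusted p = 0.107), interferon response (4 and 1 of 25; 0.436), lymphoid (2 and 1 of 30; 0.38), erythroid and megakaryocyte (1 and 2 of 27; 0.288), Hox genes (4 and 0 of 30; 0.237) or silent developmental regulators (0 and 1 of 27; 0.106). Over the list alone these counts were 7 and 0, 1 and 0, 1 and 1, 1 and 0, 2 and 0, and 0 and 0. Single members passed by edgeR, such as Nfe2, an erythroid transcription factor gene (2.69 ± 0.83), Flt3, a progenitor receptor gene (2.26 ± 0.55), and Rag1, a recombinase gene (-1.72 ± 0.48), but receptor scaling ended the calls of Nfe2 and Rag1. With an estimated correlation the adjusted p of these 6 lists ran from 0.548 to 0.722. Fry, which tests whether a list moves on balance in one direction, passed for none of the 15 lists in any region class.

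**Figure D2:**
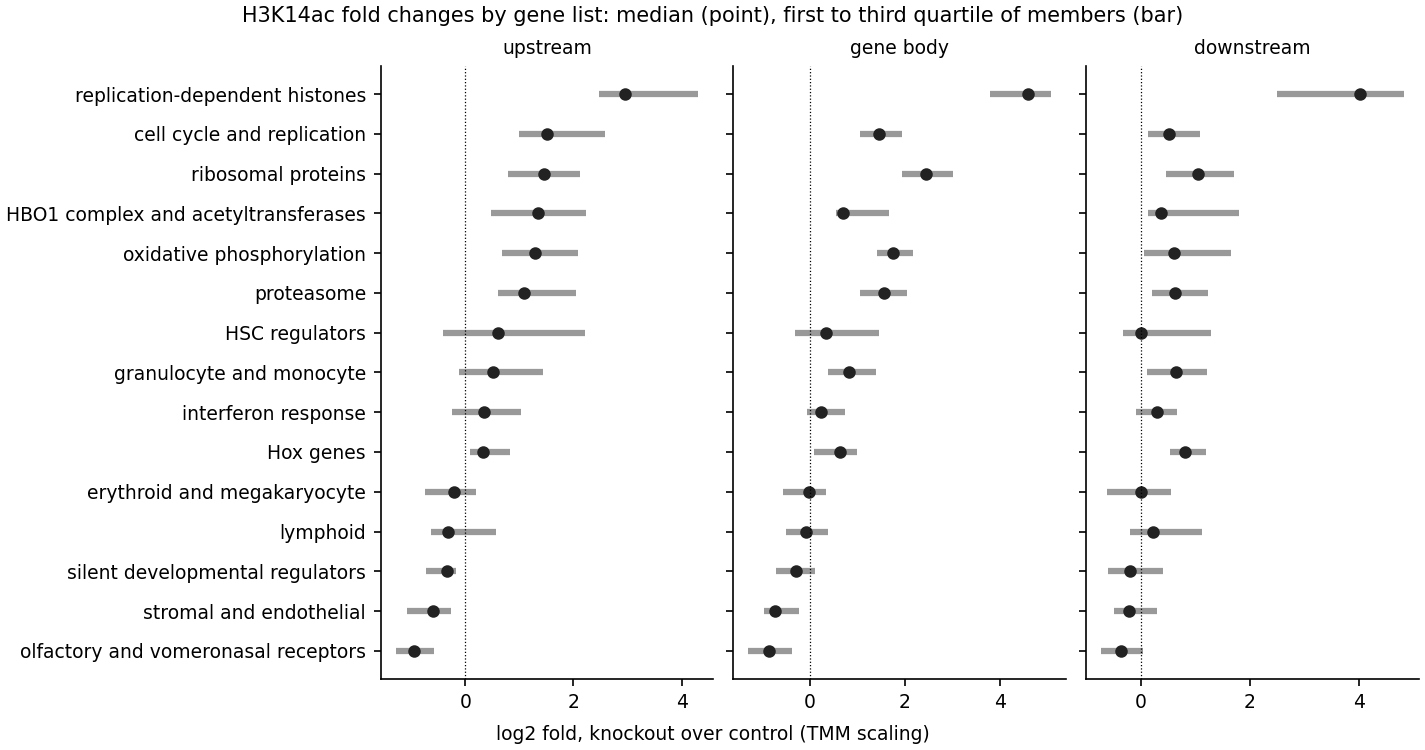
Log2 fold of H3K14ac, knockout over control with TMM scaling (horizontal axis), for 15 gene lists in 3 region classes; points are medians over members and bars run from the first to the third quartile. Replication-dependent histones stand highest (medians 2.96, 4.59 and 4.02) and receptor genes lowest (-0.96, -0.86 and -0.36, or -0.47, -0.78 and -0.07 with a GC correction, where stromal and silent developmental genes are lower upstream and downstream); with receptor scaling the upstream medians of the stromal, lymphoid, erythroid and silent developmental lists turn above 0.

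Over gene bodies, the 10 named genes that rose most included long non-coding RNA genes. Neat1 (chromosome 19, 5824708 to 5845480) rose from 3.31 ± 0.21 to 93.6 ± 83.4 CPM (SD, n = 2 each; log2 fold 4.81 ± 0.42 SE, edgeR adjusted p = 2.0e-14), and Malat1 by a log2 fold of 4.04. Kdm6b, an H3K27 demethylase gene (4.53), Bbc3, a pro-apoptotic gene (4.46), Cdkn1b, a cell cycle inhibitor gene (4.29), and Pgam1, of glycolysis (4.25), also rose, as did Tgif1, Arrdc3, Mafg and Trib1. Olfm4, a secreted glycoprotein gene, fell from 48.2 ± 9.80 to 10.98 ± 3.24 CPM (log2 fold -2.13 ± 0.35 SE, edgeR adjusted p = 2.3e-06), and Gli2, a hedgehog pathway transcription factor gene, from 757 ± 264 to 219 ± 64.1 CPM. Sntg2, Kif12, Mpped2, Nobox, Plaat1, Fbxl7, Marchf11 and Pappa fell by log2 folds between -1.93 and -1.72. The 10 named rises kept their calls with any library left out, with log2 folds from 2.82 (Mafg) to 3.59 (Kdm6b) and 3.41 for Neat1 without knockout replicate 1, and from 4.66 (Trib1) to 5.57 (Neat1) without knockout replicate 2. Gli2, Kif12, Nobox, Plaat1 and Pappa lost their calls without control replicate 1, and Kif12, Nobox and Plaat1 with receptor scaling.

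By edgeR, 8195 of 21393 gene bodies passed, 4935 higher and 3260 lower, and in 80% the groups did not overlap, against 33.3% by chance. The gene bodies without overlap were split more evenly, with 8679 higher and 8439 lower, and the median log2 fold of all was 0.02. The split of calls was 6377 and 990 with library totals, 5666 and 1360 with pooled totals, and 4481 and 186 with receptor scaling. With 1 library left out the count was 1430 without control replicate 1, 3758 without control replicate 2, 3656 without knockout replicate 1 and 11313 without knockout replicate 2.

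HSC regulators moved both ways over gene bodies: 15 of 37 rose, 5 fell and 17 did not pass (16 and 5 adjusted over the list alone), and camera did not pass (adjusted p = 0.0769, and adjusted p = 0.544 with an estimated correlation). Among those that fell were Prdm16 (log2 fold -1.13 ± 0.35), Fgd5 (-0.94 ± 0.30), Tek (-0.89 ± 0.31) and Slamf1 (-0.73 ± 0.30), and each of these lost its call with receptor scaling, with log2 folds of -0.47, -0.28, -0.25 and -0.10. The same 4 lost their calls without knockout replicate 1, and without either control. Fgd5, Tek and Slamf1 lost theirs with library totals (-0.58, -0.52 and -0.38) and pooled totals (-0.70, -0.64 and -0.50), and Slamf1 also by the DESeq2 Wald test, with no filter, with the stricter filter and with the GC correction. Risers included Erg (1.22 ± 0.34), Runx1 (0.97 ± 0.34), Lmo2 (1.45 ± 0.31) and Gata2 (1.42 ± 0.41), all transcriptional regulators of blood cells, and Cdkn1a, a cell cycle inhibitor gene (2.55 ± 0.37). Of the 20 calls of the list, rises and falls together, 14 were lost without control replicate 1, 12 without control replicate 2 and 11 without knockout replicate 1, among them Erg, Runx1 and Gata2 each time and Lmo2 without knockout replicate 1. The Gata2 call was also lost with a GC correction (log2 fold 0.64).

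Of replication-dependent histones 44 of 45 rose (median log2 fold 4.59, and 3.21 with a GC correction added after seeing the data), of ribosomal protein genes 72 of 77 (2.45), of oxidative phosphorylation genes 59 of 72, with 1 lower (1.75), of proteasome genes 28 of 39 (1.56), of cell cycle genes 29 of 38 (1.45) and of the HBO1 complex and acetyltransferases 7 of 18 (0.70). Over the list alone the higher counts were 44, 73, 62, 31, 31 and 8. Of all 9457 gene bodies of genes with a CpG-rich start site, 36.7% rose and 8.3% fell. Granulocyte and monocyte genes gave 9 higher and 0 lower of 25 (7 and 0 over the list alone; camera adjusted p = 0.0112), with Mpo, the myeloperoxidase gene (1.79 ± 0.34, a call lost without knockout replicate 1 and by the DESeq2 Wald test), and Hox genes 4 and 0 of 20 (4 and 0; 0.0367), with Hoxb4 (3.31 ± 0.57); the Hox median of 0.63 was 0.25 with the GC correction. Stromal and endothelial genes gave 10 lower and 1 higher of 19 (11 and 1; 0.00215), among them Sparc (-1.08 ± 0.30) and Pdgfra (-0.99 ± 0.30), whose calls were lost with receptor scaling and library totals, and receptor genes 100 lower and 0 higher of 535 (27 and 0; 1.3e-16). Camera passed for these 10 lists and for none with an estimated correlation, where the lowest adjusted p was 0.544. It did not pass for erythroid and megakaryocyte genes (3 higher, 4 lower of 24; adjusted p = 0.553), lymphoid genes (4 and 4 of 29; 0.42), interferon response (5 and 0 of 24; 0.186) or silent developmental regulators (0 and 4 of 22; 0.113), whose counts over the list alone were 3 and 4, 4 and 4, 5 and 0, and 0 and 3. The means of the erythroid and the lymphoid list, 0.06 and 0.02, had the opposite sign of their medians, -0.03 and -0.08. Of genes tested in both region classes 2982 rose in both, against 1217.2 if independent, and 1453 fell in both, against 423.6; the classes come from the same libraries, so part of the excess may be shared noise.

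Downstream of genes, calls of a rise outnumbered those of a fall, and the 5 named genes that rose most each held the start site of another gene in the 5 kb counted. Prdx2, a peroxiredoxin gene, went from 7.91 ± 1.23 to 432 ± 388 CPM (SD, n = 2 each; log2 fold 5.75 ± 1.05 SE, edgeR adjusted p = 0.00169), and H4c8, Gps2, Zfp36 and Zfp384 rose by 5.73, 5.36, 5.20 and 5.13. Elovl4, a fatty acid elongase gene, went from 99.4 ± 18.8 to 22.6 ± 10.9 CPM (-2.09 ± 0.41, edgeR adjusted p = 0.00245), and Capza3, Ddi1, Nectin3 and Nphp4 fell by log2 folds between -2.16 and -1.95. The 5 kb downstream of Capza3 overlaps the 5 kb upstream of Plcz1, so the falls of these genes share reads. By edgeR 2831 of 21566 regions passed, 2338 higher and 493 lower, with 62.6% not overlapping against 33.3% by chance. The regions without overlap were split the other way, with 6454 higher and 7046 lower, and the median log2 fold of all downstream regions was -0.03. The split was 2115 and 943 with library totals and 2098 and 60 with receptor scaling. Another test, the DESeq2 Wald test with its own size factors, gave 1936 and 54, where these size factors in edgeR gave 2183 and 324. Without regions that hold another gene's start site, an alternative added after seeing the data, 1517 passed. With either control library left out, the log2 folds of the 5 named rises ran from 4.89 (Zfp384) to 5.95 (H4c8). The 5 named rises lost their calls without either control library, and Capza3, Ddi1, Nectin3 and Nphp4 theirs without control replicate 1. The count was 695 without control replicate 1, 1802 without knockout replicate 1 and 4933 without knockout replicate 2.

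By list, downstream regions of replication-dependent histones gave 36 higher and 0 lower of 44 (39 and 0 adjusted over the list alone), ribosomal protein genes 15 and 0 of 57 (23 and 0), oxidative phosphorylation 14 and 0 of 55 (15 and 0), cell cycle 6 and 0 of 32 (6 and 0), proteasome 5 and 0 of 32 (7 and 1), the HBO1 complex and acetyltransferases 5 and 0 of 17 (5 and 0), granulocyte and monocyte genes 5 and 0 of 23 (5 and 0) and Hox genes 3 and 0 of 27 (3 and 0). Receptor genes gave 2 higher and 20 lower of 761 (0 and 0). Camera passed for these 9 lists, with adjusted p between 2.8e-22 and 0.00709, and for none with an estimated correlation, where the lowest adjusted p was 0.416. It did not pass for HSC regulators (9 higher, 1 lower of 38; adjusted p = 0.19), lymphoid (5 and 0 of 27; 0.143), interferon response (3 and 0 of 24; 0.177), erythroid and megakaryocyte (4 and 0 of 26; 0.985), stromal and endothelial (0 and 0 of 20; 0.31) or silent developmental regulators (1 and 0 of 28; 0.484). Over the list alone these counts were 9 and 1, 5 and 0, 3 and 0, 4 and 0, 0 and 0, and 0 and 0. The erythroid mean of 0.18 stood beside a median of 0. Of all 8486 downstream regions of genes with a CpG-rich start site, 14.5% rose and 1.2% fell.

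A ratio within each library needs no scaling between libraries. The mean upstream count per kb of cell cycle genes over that of receptor genes was 0.88 ± 0.18 in controls and 7.36 ± 5.72 in knockouts (SD, n = 2 each), that of ribosomal protein genes 0.72 ± 0.10 and 3.61 ± 2.27, and that of HSC regulators 2.29 ± 0.10 and 13.90 ± 9.73. For silent developmental regulators it was 0.81 ± 0.08 and 1.25 ± 0.37, and for stromal and endothelial genes 2.37 ± 0.09 and 3.13 ± 0.86. The mean of HSC regulators leans on a few genes. In knockout replicate 1, Zfp36 held 1422 upstream counts, Fos 905, Junb 606 and Egr1 451. In control replicate 1 these genes held 32, 34, 42 and 30. The median upstream log2 fold of HSC regulators was 0.61. Upstream and over gene bodies both knockout libraries exceeded both controls for each of 14 lists, and downstream for 13, with silent developmental regulators as the exception (1.94 ± 0.16 and 2.01 ± 0.08). All 14 ratios share the receptor genes as denominator, so the lists do not count as 14 separate results. With TMM scaling the receptor genes had the lowest upstream median log2 fold, -0.96. A list that fell less than the receptor genes can also rise in this ratio. The stromal, silent developmental, lymphoid and erythroid lists had negative upstream medians (-0.60, -0.35, -0.33 and -0.22), and the rest of the 14 had positive ones. The knockout ratio was 4.23 times the control ratio upstream, 4.03 times over gene bodies and 2.45 times downstream, as medians over the lists. With 1 library left out, the median log2 ratio of knockout over control ranged from 1.45 to 2.68 upstream, 1.6 to 2.89 over gene bodies and 0.62 to 1.48 downstream. The exact two-sided permutation p was 0.333 for each upstream and gene body ratio, the smallest possible. With medians over genes in place of means, the stromal and endothelial lists turned lower in all 3 region classes and the silent developmental regulators upstream.

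**Figure D3:**
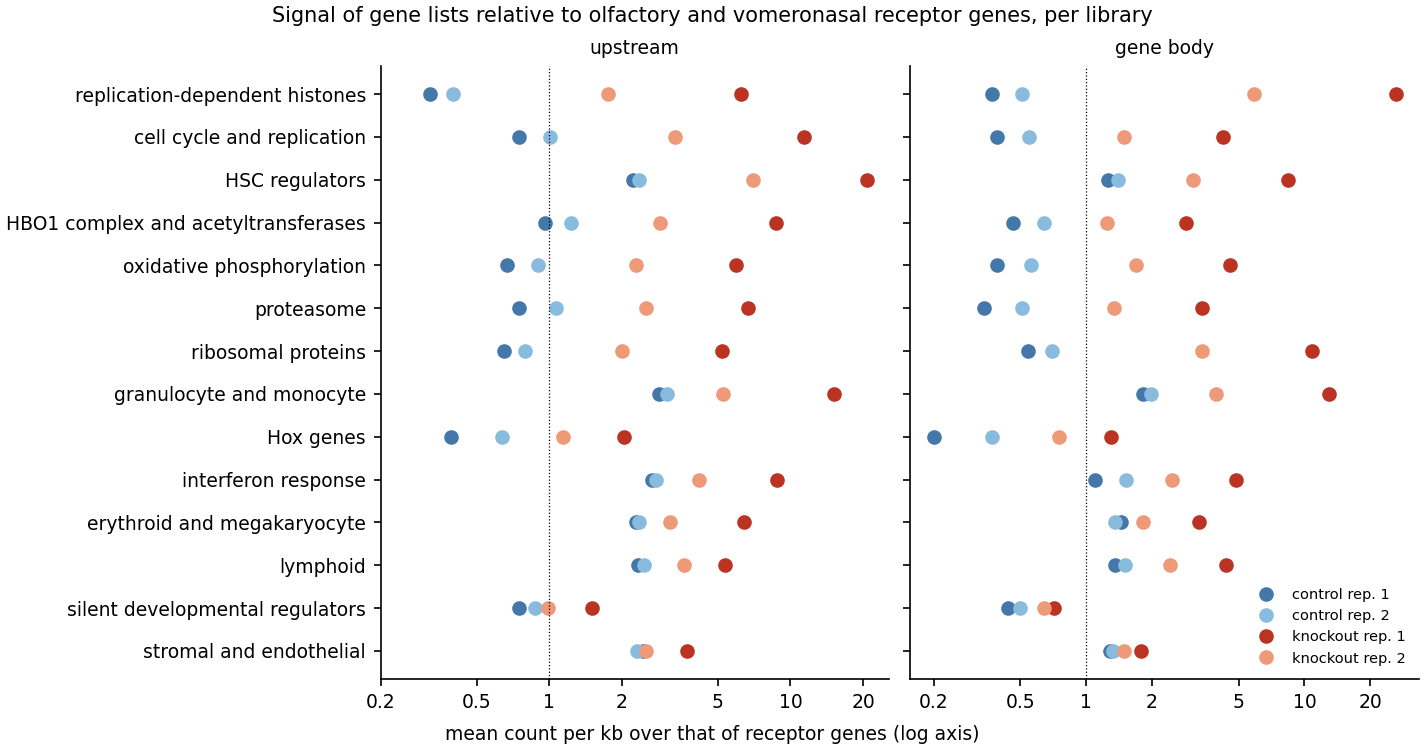
Mean count per kb of 14 gene lists over that of olfactory and vomeronasal receptor genes (log horizontal axis), upstream and over gene bodies, 1 point per library. Cell cycle genes lie at 0.75 and 1.01 in the control libraries and at 11.40 and 3.32 in the knockout libraries upstream.

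By H3K14ac level, gene bodies with intermediate to low signal had folds above 0 and those with the most signal folds below 0. In 10 bins of mean log2 CPM, the median log2 fold of gene bodies was -0.13 in bin 1, 0.82 in bin 3 (range over library pairs 0.38 to 1.17) and -0.63 in bin 10 (-0.92 to -0.32), where 56 genes rose and 881 fell. Upstream it was 0.26 in bin 3 (0.08 to 0.38) and -0.43 in bin 10 (-0.58 to -0.17), and downstream 0.37 in bin 1 (0.16 to 0.50) and -0.29 in bin 10 (-0.45 to -0.10). Calls in bin 10 went against the median in these region classes, with 572 higher and 307 lower upstream and 281 and 11 downstream. With receptor scaling the median log2 folds of bin 10 became 0.51 upstream, 0.03 over gene bodies and 0.02 downstream, so the sign of the top bin depended on the scaling. CPM was not divided by gene length, so the gene body bins also sort genes by length: the median CPM in control replicate 1 was 1.94 in the shortest of 5 length bins and 108 in the longest, where 234 genes rose and 1385 fell.

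**Figure D4:**
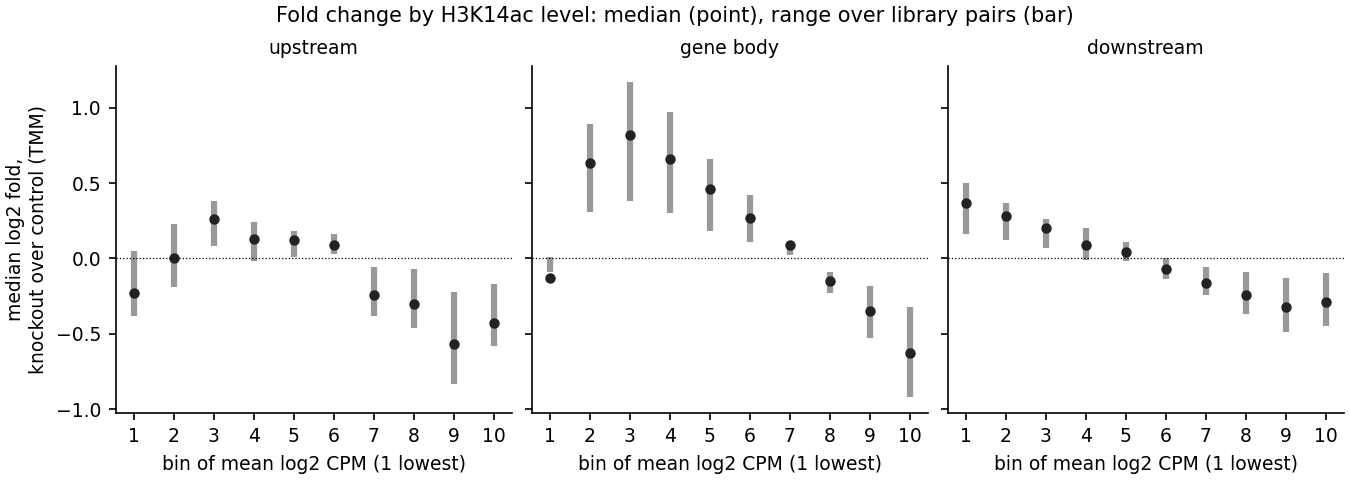
Median log2 fold of H3K14ac, knockout over control with TMM scaling (vertical axis), in 10 bins of mean log2 CPM (bin 1 lowest); bars give the range over the library pairs. Over gene bodies the median goes from 0.82 in bin 3 to -0.63 in bin 10, which receptor scaling turns to 0.03.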

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

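No planned or added setting turned the direction of a named gene's fold, where either fit called it. Among named genes, alternatives ended a call 482 times and added one 16 times; 226 of the camera results for lists stayed on their side of the threshold, 36 lost it and 8 gained it. A mean count of at least 50 tests fewer genes, and a left-out library leaves a lone sample assumed to vary like the other group. For the other changes below, the cause was not tested.

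Upstream, regions past the threshold ranged from 0 to 2303 with 1 library left out (higher 0 to 2289, lower 0 to 270), and were 3357 (2370 higher, 987 lower) at a mean count of at least 50. Lower calls numbered 458 with pooled totals, 38 with receptor scaling and 1454 by the DESeq2 Wald test. Gene bodies past it ranged from 1430 to 11313 (higher 1409 to 6622, lower 21 to 4691). They were 4667 with receptor scaling and 5426 at the stricter filter, and lower calls numbered 990 with library totals, 1360 with pooled totals, 186 with receptor scaling and 2117 at the stricter filter. Downstream the count ranged from 695 to 4933 (higher 667 to 3517, lower 28 to 1416). It was 1089 (965 higher, 124 lower) at the stricter filter and 1517 (1153 higher) without regions holding another start site; lower calls numbered 943 with library totals, 324 with DESeq2 size factors, 60 with receptor scaling, 54 by the DESeq2 Wald test and 209 with no filter.

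The labels give both groups replicate numbers 1 and 2, and no label says that they pair. The library numbers in the column names run in sets of 1 control and 1 knockout library of the same replicate number, a hint at joint processing that no label explains. With a replicate block, 4353 upstream regions passed (3474 higher, 879 lower), 3679 gene bodies (2792 higher, 887 lower) and 2408 downstream regions (310 lower). The block ended 11 of the 20 gene body calls of HSC regulators, 7 of 17 upstream, the gene body call of Kat7 and the downstream call of Zfp36. Same-numbered libraries deviated with a correlation of -0.28, -0.36 and -0.22. A crossed replicate block, added after seeing the data, gave 11874 (5420 lower), 12047 (5549 lower) and 5187 (1873 lower).

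Camera passed for 9, 10 and 9 lists in the 3 region classes and for 0 in each with an estimated correlation. The latter test has little power with so few libraries, while the preset correlation of 0.01 lay below most estimates. The downstream share differed by 0.517 points without the 1% of genes with the highest counts. The median log2 ratio to receptor genes, 2.064 upstream and 2.245 over gene bodies, was 1.409 and 1.505 with medians over genes, and 1.383 upstream against silent developmental regulators. The stromal list turned to -0.043 upstream, -0.124 over gene bodies and -0.183 downstream with medians over genes, and to -0.23 upstream and -0.199 over gene bodies against silent developmental regulators; the latter list turned to -0.093 upstream with medians. In level bin 1 the median log2 fold was 0.708 upstream, 0.527 over gene bodies and 0.687 downstream with receptor scaling, and 0.224 over gene bodies and 0.151 downstream with library totals. In bin 10 it was 0.508, 0.027 and 0.024 with receptor scaling and -0.615, -0.276 and -0.512 with library totals. With 1 library left out, bin 1 ranged from -0.351 to -0.005 upstream, -0.116 to 0.011 over gene bodies (0.011 without knockout replicate 1) and 0.102 to 0.486 downstream.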

Other observations

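The tests below were chosen after the patterns were seen, except the first 2 on gene length, whose predictions were written before their results. Genes split by the CpG content of their start site moved apart. Of 9350 upstream regions of genes with a CpG-rich start site (observed over expected ratio of at least 0.6), 4059 rose and 293 fell, with a median log2 fold of 0.95 (range over library pairs 0.57 to 1.21). Of 12461 with a CpG-poor start site, 1341 rose and 2767 fell, with a median of -0.66 (-0.93 to -0.31). Small nucleolar RNA genes, often hosted in genes of the translation machinery, gave 27 higher and 2 lower of 47 upstream regions (median 1.47), and long non-coding RNA genes 267 higher and 487 lower of 1884 (median -0.71). Over gene bodies long non-coding RNA genes gave 325 higher and 340 lower of 1682 (median -0.39). These directions are relative to TMM; receptor scaling moves the median of all upstream regions up by 0.92.

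The 2 knockout libraries differed in the size of the change. Over upstream regions the median absolute log2 fold against the control mean was 1.22 in knockout replicate 1 and 0.69 in knockout replicate 2. Across genes, log2 CPM of knockout replicate 1 correlated with the controls at 0.05 and 0.14 and knockout replicate 2 at 0.45 and 0.53; genes are not independent replicates.

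Upstream regions of ribosomal protein, oxidative phosphorylation, proteasome and cell cycle genes rose relative to silent genes in the knockout libraries. GC content was tested in 5 versions, each chosen after earlier results were seen: on the 115 called members the median log2 fold was 1.88 before and 1.81 after a GC correction; on all 200 tested members it was 1.23 before and 1.21 after, which the bound set for that version left undecided, because the range between library pairs (interquartile range 0.60) was wider than the margin; and within each library pair at least 94.4% of the fold was kept, at least 70.8% of the gap to receptor genes and at least 106.7% of the gap to silent developmental regulators. The shares of the fold and of the gap to silent developmental regulators could not decide this. Median upstream GC was 44.8% to 46.0% in these lists, near the 44.6% of all genes, and 48.6% in silent developmental regulators. Receptor genes had 36.9%, so the gap to them could show GC bias. The share of that gap that was kept, tried last, argues against GC content averaged over the 5 kb as its whole cause. The correction used that average alone. Around the start site the median GC was 55.4% to 57.3% in these lists and 38.4% in receptor genes. A GC bias confined to start sites therefore stays open. Part of the gap went with the correction, as the upstream median of receptor genes went from -0.96 to -0.47. Untargeted cutting of open DNA may contribute: mitochondrial genes, whose DNA carries no histones, took a share of gene body reads in the lower knockout library 3.44 times that in the higher control, yet the knockout library with the larger rise had 0.97 times the mitochondrial share of the other, so this share did not track the size of the rise. A redistribution of H3K14ac with the genotype stays open and untested, since no spike-in or untargeted control library was analysed here.

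Part of the rise of downstream regions may come from start sites of neighbouring genes inside the 5 kb. Of regions that hold one, 45.6% of 2964 rose, and of those that hold none, 4.8% of 17206, a ratio of 0.11. Among those that hold none, 820 rose and 444 fell with TMM scaling, so such start sites leave part of the excess of called rises unaccounted for. The median log2 fold of the regions that hold none was nevertheless -0.13 (range over library pairs -0.22 to -0.06). The test does not say why start sites rose, and a biological explanation for the downstream regions themselves was not tested.

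Gene body folds fell with gene length among genes with a CpG-rich start site, while over all genes the medians of the 5 length bins were 0.01, 0.34, 0.34, 0.11 and -0.41, with no steady fall. In the former genes the median log2 fold was 1.95 in the shortest of 5 length bins and -0.30 in the longest, a difference of 2.25, which may reflect a fixed number of gained reads near the start site that is diluted in longer genes. GC content of the gene body could account for most of the smaller difference between the shortest and the longest bin of all genes on the log2 CPM scale, which went from 0.43 to 0.14 after a GC correction. Among genes with a CpG-rich start site the difference went from 2.05 to 1.67 on that scale. This argues against GC content averaged over the gene body as the whole cause there. A change of H3K14ac along gene bodies with the genotype stays open, since the counts do not show where in a gene the reads lie.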
